A study of Rattus norvegicus with 6 samples.

How the data were processed

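CUT&Tag was run on rat tenocytes with antibodies against H3K9la, H4K8la and H4K16la, each on untreated cells and on cells given 20 mM lactate, which makes 6 libraries in 6 groups of 1. Groups were taken from the sample titles, which match the treatment entry of each sample. The free-text treatment field names 20 mM lactate for all 6 libraries and was not used to assign groups. Per the submitters' processing notes, FastQC, cutadapt, Bowtie2, deepTools and MACS2 were used and the build was rn7. Their versions, settings and roles are not given in the sources used here. The labels' protocols mention an IgG control antibody, but whether an IgG library entered peak calling is not given in the sources used here.

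Each library has its own deposited list of narrow peaks, so peaks were called per library and not on pooled samples. The authors' score column is a whole number that equals 10 times the −log10 q without its decimals. The fold column, as deposited by the authors, is a ratio of the pileup at the summit to the local background. The authors' −log10 p and −log10 q columns are statistics of the peak caller for each peak, and the lowest deposited −log10 q in each list was 1.30 or 1.31, which corresponds to a q of 0.05. The remaining deposited columns hold positions and the distance of the summit from the peak start. All these values belong to single peaks and were used only to describe, rank or filter peaks within a list, or for the depth calculation described here. No peak lay outside chromosomes 1 to 20, X and Y, and no peaks of a list overlapped each other.

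Peaks of a pair of lists were called shared when they overlapped by at least 1 bp. The share expected by chance came from 20 shuffles that moved each peak to a random place on its chromosome. Regions across all 6 lists were made by merging overlapping peaks, and a mark was called control only or lactate only in a region when just 1 of its 2 lists had a peak there. Shares have Wilson 95% intervals, and intervals of log2 ratios of peak numbers come from the Wilson interval of the lactate share of both lists. Overlapping fragments and PCR copies are not independent, so all intervals cover counting error only. With 1 library per group no test between conditions was made.

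Depth was recovered from the lists. The caller's fold was taken as (pileup + 1) over (local background + 1), and its p as the upper Poisson tail of the pileup given that background. For each peak the whole-number pileup was sought for which both deposited values hold within 0.002 of −log10 p. One was found for every peak of 5 libraries and for 62562 of the 62563 peaks of H4K16la lactate. The most frequent local background of a library, shared by 4839 to 10977 peaks, was taken as its genome-wide background, that is the mean coverage by fragments. If an IgG library entered peak calling, the local background of a peak would come partly from it. This reading of the columns is inferred from the values and not stated in the labels. To match depth, the summit pileups of the deeper library of a pair were thinned to the lower background in 20 binomial draws. Its local backgrounds were scaled by the same ratio without draws. Peaks were then counted again at −log10 p of at least 4 and of at least 10. Thinning keeps the original summit and cannot bring in a region that was below the authors' threshold, so it undercounts the thinned library at both thresholds. On simulated peaks, picking the summit again after thinning raised the pileup by a factor of 1.01 for the H3K9la and H4K8la depth ratios and 1.06 for that of H4K16la, and counts with that factor are given as an allowance. The pileup search was also run 6 times on 5000 simulated peaks, made with these same formulas and with settings not taken from the libraries. It returned 100% of the simulated pileups. This shows only that the search solves the formulas, and it cannot test whether the deposited columns follow them.

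Peaks named in the text were chosen by a rule fixed before the data were examined. It takes the 8 peaks of highest −log10 q found in 1 list only, per mark and direction. Regions named across marks are those of highest mean −log10 q in each arrangement, a rule set after the data were seen. The thresholds of −log10 q of at least 5 and 10, equal numbers of peaks, an overlap of at least 50% of the shorter peak, peak centres within 500 bp, covered bases in place of peak numbers, unmerged lines and all sequences were also fixed before the data were examined. The depth-matched counts and the −log10 p thresholds were added after seeing the data. Promoter peaks, genes and the 26 gene lists fixed beforehand were not analysed here, because the gene table at hand describes assembly GRCr8 and positions of different builds cannot be combined. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.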

Results

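CUT&Tag profiles of 3 histone lactylation marks, H3K9la, H4K8la and H4K16la, were collected from rat tenocytes, the fibroblast-like cells that build and maintain tendon. Lactylation is the addition of a lactyl group, which derives from lactate, to a lysine side chain. In CUT&Tag an antibody against the mark directs a transposase to the chromatin that carries it, and the released fragments are sequenced. For each mark there was 1 library of untreated cells (control) and 1 library of cells given 20 mM lactate, 6 libraries in all. The submitters' stated aim was to relate lactylation to the genes it regulates. There were no replicates, so no difference between libraries has a replicate check, no p-value was computed, and every interval covers counting error only. Regions are given by position (build rn7, counted from 1). No annotation of that build was used here, so no gene, exon or intron is assigned to them.

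The peak lists held 61850 peaks for H3K9la control, 46597 for H3K9la lactate, 61347 for H4K8la control, 42787 for H4K8la lactate, 40681 for H4K16la control and 62563 for H4K16la lactate. Median peak width lay between 448 and 500 bp in all 6 lists. Read totals are not part of the lists. Depth was therefore read from the background coverage recovered from each list, the mean number of fragments over a base. It was 2.17 in H3K9la control and 1.88 with lactate, 1.32 in H4K8la control and 1.55 with lactate, and 1.53 in H4K16la control and 2.84 with lactate.

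**Figure D1:**
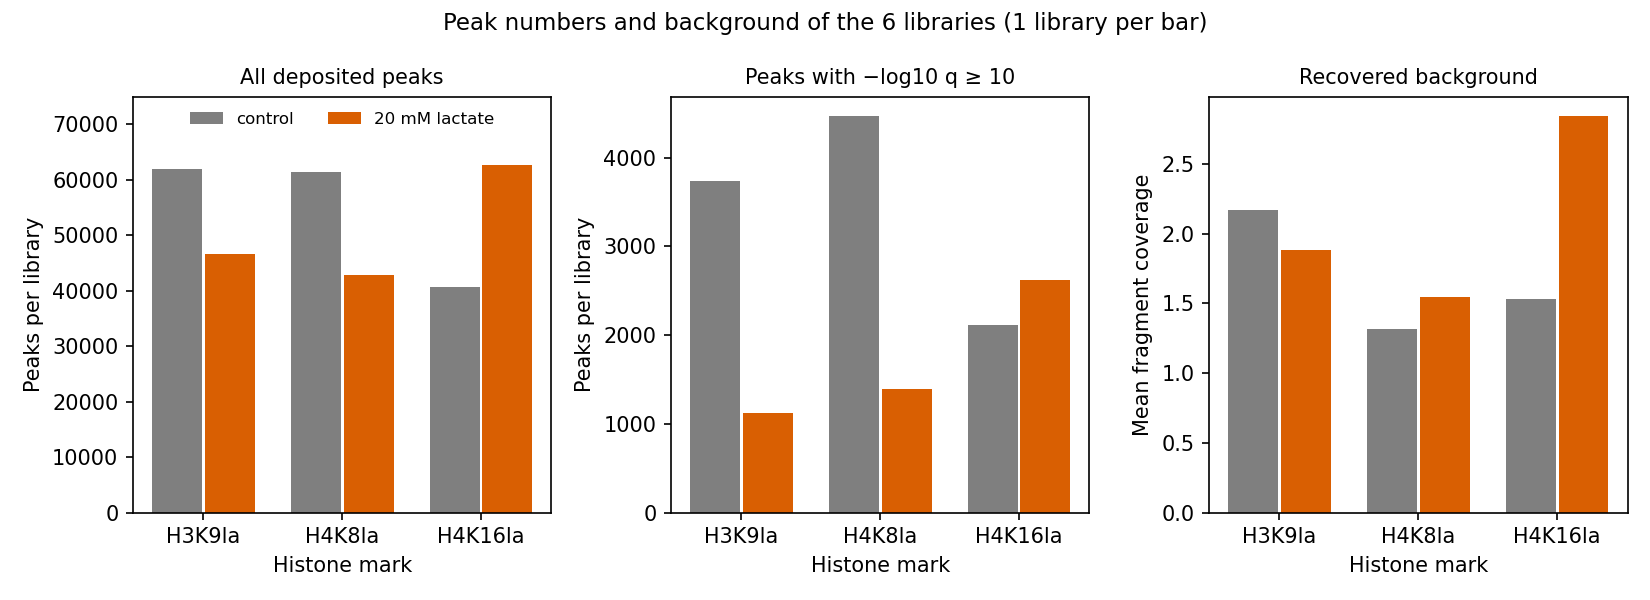
Peaks per library (left), peaks with −log10 q of at least 10 (middle) and the recovered background in mean fragments per base (right), for control (grey) and 20 mM lactate (orange), 1 library per bar and no error bars. Peak numbers were lower with lactate for H3K9la and H4K8la and higher for H4K16la, whose lactate library had a background of 2.84 against 1.53 in control.

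H3K9la was called at fewer regions in the lactate library than in control. The log2 ratio of peak numbers was −0.41 (95% counting interval −0.43 to −0.39), and the peaks covered 23.6 Mb with lactate and 35.5 Mb in control. The gap was wider among strong peaks, with 1124 against 3735 at −log10 q of at least 10, a log2 ratio of −1.73. Of the control peaks, 34.3% (Wilson 95% interval 34.0 to 34.7) overlapped a lactate peak, and 45.8% (45.3 to 46.2) of the lactate peaks overlapped a control peak. Shuffled positions gave 2.02% and 2.69%. Of the peaks with −log10 q of at least 10, 85.7% in control and 96.0% with lactate overlapped some peak of the other list, but 18.0% and 60.0% overlapped a peak that itself reached this threshold. With 1124 such lactate peaks for 3735 in control, list length by itself limits the control share. Control peaks without a lactate partner were weaker and narrower than those with one, with a median −log10 q of 3.21 against 5.49 and a median width of 448 against 641 bp.

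The strongest H3K9la peak found in control only lay on chromosome 4 from 146176585 to 146177230, with a fold of 6.69 over local background and a −log10 q of 23.5. Among the other marks it had a peak in the H4K16la lactate library alone. The next, on chromosome 12 from 11721517 to 11722310, had the highest fold of the 8 named (9.34, −log10 q 20.1) and carried a peak in all 4 libraries of the other marks, lactate included. Across the 8 strongest control-only peaks, −log10 q ran from 18.7 to 23.5, and the nearest lactate peak was at least 8237 bp away. The strongest lactate-only peak, on chromosome 9 from 10061097 to 10061894 (fold 7.60, −log10 q 27.8), lay 33 bp from a control peak. The lactate-only peak on chromosome 14 from 46237362 to 46237738 (fold 9.72, −log10 q 17.4) was 1855977 bp from the nearest H3K9la control peak, yet all 4 libraries of the other marks had a peak there. On chromosome 5 from 119779491 to 119779864 (fold 9.26, −log10 q 17.1) the lactate-only peak was found in no other library. Of the 8 strongest lactate-only peaks, 4 lay within 5 kb of an H3K9la control peak, and 7 had a peak in at least 1 library of another mark.

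The H3K9la lactate library was the shallower of its pair. With control summits thinned to its background, the log2 ratio was −0.22 at −log10 p of at least 4 and −0.63 at 10, so the direction was kept and the size fell. The allowance for summits that move after thinning gave −0.24 and −0.71.

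H4K8la was also called at fewer regions with lactate. The log2 ratio of peak numbers was −0.52 (−0.54 to −0.50), and the peaks covered 23.0 Mb with lactate and 36.5 Mb in control. At −log10 q of at least 10 there were 1387 peaks with lactate and 4465 in control, a log2 ratio of −1.69. Lactate peaks were found at 29.6% (29.2 to 30.0) of the control peaks and control peaks at 42.6% (42.1 to 43.0) of the lactate peaks, against 1.92% and 2.80% for shuffled positions. Of these strong peaks, 88.6% in control and 97.6% with lactate overlapped some peak of the other list, and 21.9% and 70.4% a peak that also reached this threshold. Here too the unequal list lengths limit the control share. Control-only peaks had a median −log10 q of 3.13 and a median width of 437 bp, and shared control peaks 6.21 and 748 bp. The lactate library was the deeper of this pair, and with its summits thinned to the control background the log2 ratio was −0.71 at −log10 p of at least 4 and −1.62 at 10. With the same allowance it was −0.68 and −1.52.

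The strongest H4K8la peak found in control only lay on chromosome 9 from 866797 to 867802 (fold 6.37, −log10 q 30.5), and all 4 libraries of the other marks had a peak there. That held for 5 of the 8 strongest control-only peaks, among them chromosome 3 from 114340699 to 114341299 (fold 8.70, −log10 q 23.2) and chromosome 20 from 3733419 to 3734019 (fold 7.11, −log10 q 20.3). In contrast, the peak on chromosome 2 from 73364903 to 73365370, with the highest fold of the 8 (13.2, −log10 q 25.8), was found in no other library, and the nearest H4K8la lactate peak was 60425 bp away. The lactate-only peaks were led by chromosome 9 from 41396318 to 41397002 (fold 9.17, −log10 q 20.1) and chromosome 2 from 183472472 to 183472979 (fold 8.15, −log10 q 19.0), both with a peak in all 4 libraries of the other marks. On chromosome 3, 2 of the 8 strongest lactate-only peaks lay close to each other, from 1498226 to 1498710 and from 1507115 to 1508347, and the other marks had peaks at both in control and with lactate. The 8 lactate-only peaks ran from 13.3 to 20.1 in −log10 q and the 8 control-only peaks from 18.9 to 30.5.

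**Figure D2:**
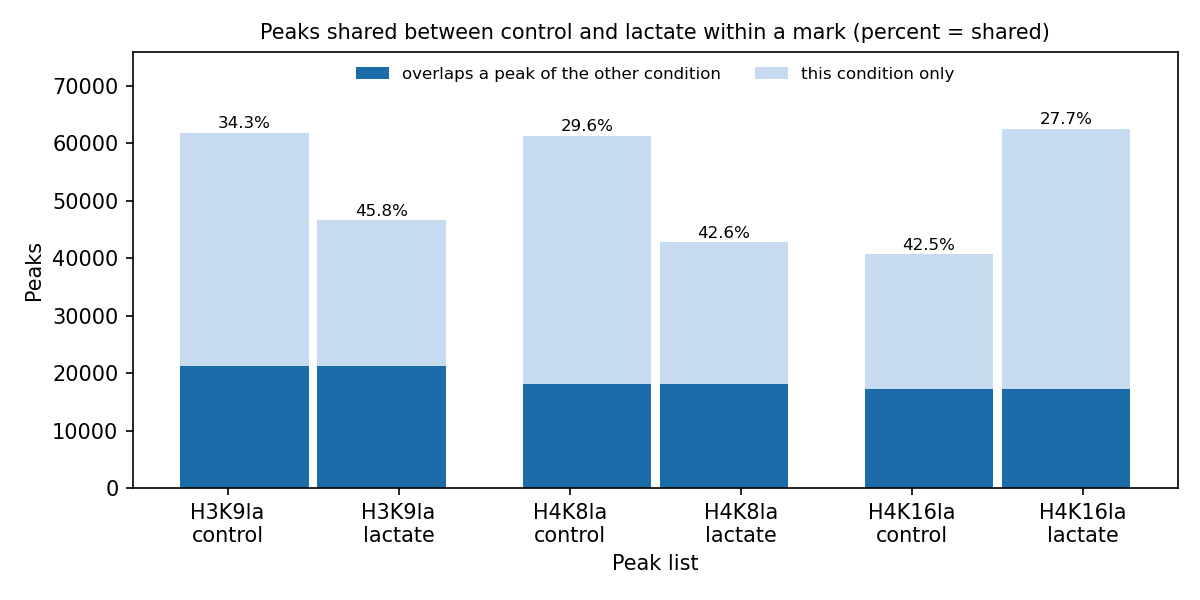
Number of peaks in each of the 6 lists, split into those that overlap a peak of the same mark in the other condition by at least 1 bp (dark) and those found in that condition only (light), with the shared percentage above each bar. Shared percentages ran from 27.7% for H4K16la lactate to 45.8% for H3K9la lactate.

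H4K16la was called at more regions with lactate, 62563 against 40681, a log2 ratio of 0.62 (0.60 to 0.64), but the lactate library was 1.86 times deeper and the gain was no longer seen at matched depth. With lactate summits thinned to the control background, the log2 ratio was −0.27 at −log10 p of at least 4 and −1.65 at 10. An allowance for summits that move after thinning, taken from simulated peaks, gave −0.07 and −1.15. At full depth the excess was smaller among strong peaks, with 2623 against 2110 at −log10 q of at least 10, a log2 ratio of 0.31. Control peaks were found at 27.7% (27.3 to 28.0) of the lactate peaks and lactate peaks at 42.5% (42.0 to 42.9) of the control peaks, against 1.65% and 2.54% for shuffled positions. Among strong peaks, 95.6% of the control peaks and 85.2% of the lactate peaks overlapped some peak of the other list, and 50.4% and 40.6% a peak that also reached −log10 q of at least 10.

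The strongest H4K16la peak found with lactate only lay on chromosome 16 from 20232336 to 20232934 (fold 10.7, −log10 q 26.7), and all 4 libraries of the other marks had a peak there. The next was on chromosome 6 from 62488376 to 62489370 (fold 9.63, −log10 q 22.4), where both H3K9la libraries had a peak and neither H4K8la library did. The peak on chromosome 12 from 21315596 to 21315915 (fold 7.09, −log10 q 21.0) was the only one of the 8 found in no other library. Control-only peaks were led by chromosome 9 from 81670357 to 81670906 (fold 9.0, −log10 q 24.7) and chromosome 1 from 153441838 to 153442542 (fold 6.58, −log10 q 21.9), the latter 828 bp from an H4K16la lactate peak. Both shared a pattern, with a peak in both H4K8la libraries and in H3K9la control but not in H3K9la lactate. The same pattern held on chromosome 5 from 161495288 to 161495897 and on chromosome 19 from 47612363 to 47612877. The control-only peak on chromosome 19 from 51575078 to 51575954 (fold 7.47, −log10 q 17.4) was found in no other library.

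**Figure D3:**
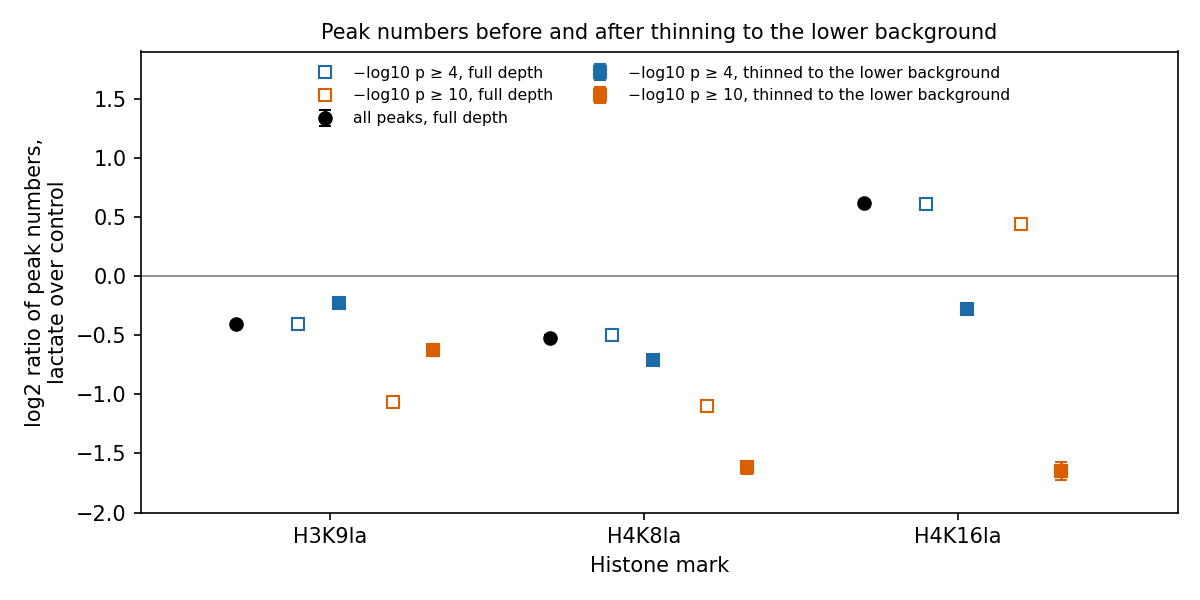
Log2 ratio of peak numbers, lactate over control, for each mark: all peaks (black circles), peaks above a −log10 p threshold at full depth (open squares) and after thinning the deeper library's summit pileups to the lower background of the pair (filled squares, mean of 20 draws), with 95% counting intervals on the filled points. H4K16la moved from 0.61 to −0.27 at −log10 p of at least 4 and from 0.44 to −1.65 at 10, while H3K9la and H4K8la stayed below 0. With the allowance for moved summits, which is not drawn, H4K16la was at −0.07 and −1.15.

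The 6 lists were then merged to ask where the marks coincide. They formed 176698 regions, of which 7268 had a peak in all 6 libraries and 117601 (66.6%) in 1 library only. In control, 14479 regions carried a peak for all 3 marks, 3.01 times the 4806 expected if the lists were drawn independently from these regions. With lactate there were 10997 such regions, 2.82 times the expected 3899. At −log10 q of at least 10 the numbers were 762 in control and 350 with lactate. Because the regions were defined by the peaks themselves, these expected numbers describe the lists and not the genome.

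The regions of highest mean −log10 q among those in all 6 libraries were on chromosome 1 from 154403659 to 154404088 (181, from 122 to 352 across libraries), on chromosome 3 from 2252034 to 2253252 (88.1) and on chromosome 1 from 209640248 to 209641544 (75.3). The first region had a summit pileup of 70.6 to 113.7 times the genome-wide background across the 6 libraries, whatever the mark or treatment. The region on chromosome 3 lay in a stretch of high coverage, with a local background 16.7 to 27.1 times the genome-wide one, and the second region on chromosome 1 in one of 13.5 to 21.5 times. No filter for artefact-prone regions was applied here, so signal unrelated to the marks was not excluded at these regions. At most of the 7268 regions common to all 6 libraries, the summit pileup relative to the library's genome-wide background was lower with lactate for each mark. This held at 69.1% of them for H3K9la (median log2 difference −0.22), 88.7% for H4K8la (−0.60) and 91.5% for H4K16la (−0.61). These pileups were not corrected for depth. Picked summits of a shallower library can stand higher over its background by counting noise alone. For H4K8la and H4K16la the shallower library was control. The fold over local background was compared in another, larger set, all peaks shared between the conditions of a mark. It did not fall for every mark. Its median at peaks shared between conditions was 3.86 with lactate and 3.76 in control for H3K9la. It was 4.13 and 4.40 for H4K8la, and 3.81 and 4.29 for H4K16la.

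Regions called in 1 condition only for all 3 marks were rare. There were 374 for lactate and 854 for control, 0.45 and 0.70 times the number expected for independent lists, and 8 and 97 at −log10 q of at least 10. The lactate-only regions were led by chromosome 9 from 98653121 to 98653969 (mean −log10 q 11.9) and chromosome 15 from 96255082 to 96255592 (11.2), and the control-only regions by chromosome 18 from 58127526 to 58128155 (10.3) and chromosome 1 from 168302862 to 168303733 (9.07). Opposite calls were more frequent in one arrangement, with 1401 regions where H4K16la was called with lactate only and both other marks in control only, and 132 with the reverse. The first set was led by chromosome 1 from 185043374 to 185044141 (12.7) and chromosome 9 from 86831349 to 86831914 (12.4). Independent lists of these sizes would give 2382 and 430, so the observed counts were 0.59 and 0.31 times the expected ones. Same-direction and opposite arrangements alike thus fell below the expected numbers. The regions were defined by the peaks themselves, so these ratios cannot show whether the marks avoid a shared direction. Pair by pair, the expected number was taken only from regions called in 1 condition only for both marks. Such regions took the same direction slightly more often than independent lists would. The observed over expected ratio was 1.07 for H3K9la with H4K8la, 1.04 for H3K9la with H4K16la and 1.06 for H4K8la with H4K16la, with odds ratios of 1.51 (1.39 to 1.63), 1.21 (1.13 to 1.31) and 1.29 (1.19 to 1.40).

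**Figure D4:**
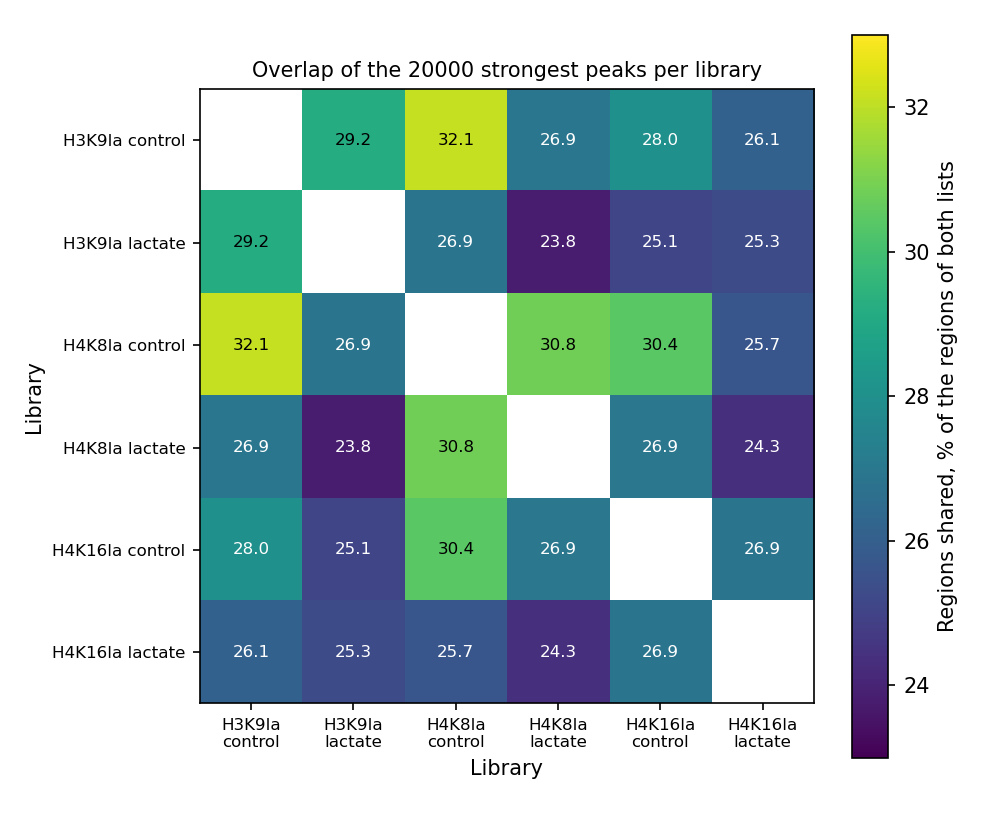
Overlap of the 20000 peaks of highest −log10 p of each pair of libraries, as the regions with a peak in both as a percentage of the regions with a peak in either (number and colour). The pair of H3K9la control and H4K8la control shared most (32.1%), above the 3 pairs of the same mark (29.2%, 30.8% and 26.9%). Each lactate list shared most with the control list of its own mark. At 40681 peaks per library, the full length of the H4K16la control list, this no longer held for H4K16la (22.6%, against 25.7% with H3K9la control).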

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

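The tests of swapped labels, of the lowest p called in the other library and of a few large loci were set before their results were seen. The other tests in this part were chosen after, as were the limit of the second of these to 3 lists and its allowance of 1 counting SD.

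The response of peak numbers to lactate differed in direction between marks, with log2 ratios of −0.41 for H3K9la, −0.52 for H4K8la and 0.62 for H4K16la. The difference between marks was not tested, since each value comes from 1 library per condition. For H4K8la, depth is an unlikely cause of the lower number, since the lactate library was 1.18 times as deep as control. That depth is inferred from the recovered background and not from read totals. At matched depth and −log10 p of at least 4 the ratio was −0.22 for H3K9la, which argues against depth as the whole cause, and −0.27 for H4K16la, whose gain was no longer seen and may come from the deeper lactate library. Thinning undercounts, and the H4K16la ratio was −0.07 with the allowance for moved summits; at −log10 p of at least 10 it was −1.65, and −1.15 with the allowance. The H4K16la pileup over background was lower with lactate at 91.5% of the regions common to all 6 libraries (median log2 difference −0.61), which goes with a ratio below 0. It rests on the same pileups and backgrounds, was not corrected for the deeper lactate library and is no separate test of that ratio. Swapped labels of the H4K16la libraries would make H4K16la run against both other marks, if lactate moved the marks alike at the same regions. Same-direction regions numbered at least 1.04 times those of independent lists. That goes against a swap only under this assumption, which was not tested. For H3K9la and H4K8la, a lower enrichment of the whole lactate library remains open. With lactate, 69.1% and 88.7% of the regions common to all 6 libraries had a lower pileup over genome-wide background. These shares were not corrected for depth, and the H4K8la lactate library was the deeper of its pair. For H3K9la, the median fold over local background at peaks shared between its conditions was 3.86 with lactate and 3.76 in control. For H4K8la that fold was 4.13 and 4.40. The H3K9la medians come from 21321 lactate and 21241 control peaks, not from the regions common to all 6 libraries. Whether the 69.1% depends on the background used was therefore not tested. An effect of lactate on the marks, which would look the same without a spike-in or replicate, also remains open and untested.

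Most peaks were found in 1 condition only, 40609 of 61850 for H3K9la control and 45245 of 62563 for H4K16la lactate, for example. Scaling to a deeper library can put no peak below the threshold, so this was tested in the 3 lists whose other library is shallower. There, scaling the summit pileup to that library put 16.4% of such peaks below the lowest p called there, a value carried by H4K16la lactate (36.5%, against 3.15% for H3K9la control and 1.37% for H4K8la lactate), and 2.48% without that list. The bound of 50% set for this test took pileups as exact, although peaks near a threshold are picked partly because their counts came out high, and with every summit lowered by 1 counting SD the share was 69.9%, or 59.0% without H4K16la lactate, so for the peaks of these 3 lists depth and the threshold cannot be told apart from a difference between conditions. In the other 3 lists, whose other library is deeper, the lowered summits gave 36.5% for H3K9la lactate, 44.0% for H4K8la control and 10.3% for H4K16la control. Among the 15444 peaks with −log10 q of at least 10, depth and Poisson counting would lose 0.247%, while 10.4% had no partner. Most of the expected loss came from H4K16la lactate (1.36% expected, 14.8% observed), and without that list 0.0193% was expected and 9.46% observed. By list the observed share ran from 2.38% to 14.8% and lay above the expected one in all 6. The expected share took each summit pileup as exact and scaled the peak's own local background, so it may be too low. Counting at these pileups does not account for the strong ones, but how far lowered summits would raise the expected share was not tested. Variation between libraries beyond counting and an effect of lactate both remain open, as the design has no replicates.

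Peaks whose local background exceeded the genome-wide one by over 5 times were frequent in H3K9la control (4801) and H4K8la control (5026) and rare in the other libraries (382 in H3K9la lactate, 231 in H4K8la lactate, 218 in H4K16la control and 67 in H4K16la lactate). Depth is an unlikely cause, because the 3 libraries with a background between those of the pair had at most 382 such peaks. A few large loci are also an unlikely cause, since the 20 fullest windows of 1 Mb held at most 11.9% of them in either library. Whether an IgG library entered peak calling is not given in the sources used here, and if one did, this local background would partly reflect IgG signal and not the mark. That, broad enrichment in these 2 libraries, a difference in library preparation and an effect of lactate on broad domains remain open, and none of them was tested.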

How the results depend on the processing

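The −log10 p thresholds and the thinned counts in this part were chosen after seeing the data. Of the 57 planned comparisons of a setting with a result, 45 moved the value beyond its counting interval or, for counts of regions, by over 1.5 times. Only the log2 ratios of peak numbers have a direction that could turn, and no planned setting turned one. The 2 reversals came from thinning H4K16la. Intervals are narrow at these peak numbers, so most shifts pass them. Including all sequences and leaving lines unmerged could change nothing, since the lists hold no other sequences and no overlapping peaks. Unless stated otherwise, the cause of a shift was not tested.

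Marks are given in the order H3K9la, H4K8la, H4K16la. The log2 ratios of peak numbers were −1.03, −1.12 and 0.56 at −log10 q of at least 5, −1.73, −1.69 and 0.31 at −log10 q of at least 10, and −0.59, −0.66 and 0.60 for covered bases. At full depth they were −1.07, −1.10 and 0.44 at −log10 p of at least 10, and that of H4K8la was −0.50 at −log10 p of at least 4. After thinning they were −0.22, −0.71 and −0.27 at −log10 p of at least 4, and −0.63, −1.62 and −1.65 at 10. For H4K16la the setting removes the excess depth of its lactate library and also undercounts the thinned list, and the cause of the turn below 0 was not tested.

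The percentages of control peaks on a lactate peak were 29.2, 31.7 and 53.7 at −log10 q of at least 5 in both lists and 18.0, 21.9 and 50.4 at 10, and those of lactate peaks on a control peak 59.7, 68.6 and 36.3, and 60.0, 70.4 and 40.6. The lists differ in length at both thresholds, which limits the share for the longer list. Equal numbers of peaks gave 41.4, 38.9 and 36.2 for control and 41.7, 39.2 and 36.2 for lactate. For lists of equal length the 2 directions come out nearly equal by construction, so this is no test of the gap between them. An overlap of 50% of the shorter peak gave 30.8, 26.4 and 37.9, and 41.0, 38.1 and 24.7. Centres within 500 bp gave 33.6 and 28.3 for control peaks and 44.6 and 40.6 for lactate peaks of H3K9la and H4K8la.

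Regions with all 3 marks numbered 4753 in control and 2776 with lactate at −log10 q of at least 5, and 762 and 350 at 10. Regions called for all 3 marks in 1 condition only numbered 460 for control and 53 for lactate at 5, and 97 and 8 at 10. With equal numbers of peaks these counts stayed within 1.5 times. Planned results on promoters, genes and the 26 gene lists, with their windows of 500 bp, 1 kb and 3 kb, were not run, since the gene table at hand describes another assembly. Depth limits the strong peaks too, since thinning took H4K16la lactate from 58839 to 31887 peaks at −log10 p of at least 4 and from 8109 to 1902 at 10.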

Other observations

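Peaks were spread widely, and the 20 fullest windows of 100 kb held 1115 of the 315825 peaks of the 6 lists (0.353%). The first of these lay on chromosome 16 from 20200001 to 20300000, with 87 peaks in all and between 12 and 18 in each library. It also holds the strongest H4K16la peak found with lactate only. Next came windows on chromosome 3 from 11100001 to 11200000 with 64 peaks and on chromosome 10 from 103600001 to 103700000 with 61. The window on chromosome 19 from 23300001 to 23400000 had 11 peaks in H3K9la control and 2 with lactate, 16 in H4K8la control and 7 with lactate, and 8 in each H4K16la library.

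The control lists of different marks overlapped about as much as the lists of the same mark. At 20000 peaks per library, the control libraries of different marks shared 32.1%, 28.0% and 30.4% of their regions, the lactate libraries of different marks 23.8%, 25.3% and 24.3%, and the 2 libraries of the same mark 29.2% for H3K9la, 30.8% for H4K8la and 26.9% for H4K16la. At this size each lactate list shared most with the control list of its own mark, whereas the H3K9la control list shared more with H4K8la control and the H4K16la control list more with both other controls. At 40681 peaks per library, the same-mark pairs shared 27.6%, 25.6% and 22.6%, and the control pairs of different marks 32.0%, 25.2% and 25.0%, so the same-mark pairs of H3K9la and H4K8la then stood above all control pairs but that of H3K9la with H4K8la. H4K16la lactate then shared more with H3K9la control (25.7%), H4K8la control (24.1%) and H3K9la lactate (23.4%) than with its own control. This size takes the whole H4K16la control list, weakest calls included, but only the strongest peaks of the longer lists. Whether that lowers its overlaps was not tested.

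Peaks of 1 kb or wider made up 7.68% of H3K9la control and 11.1% of H4K8la control, and between 3.28% and 5.27% of the other 4 lists. Of the peaks with a high local background in H3K9la control, 63.4% overlapped an H4K8la control peak, against 40.5% of its other peaks, 48.0% overlapped an H3K9la lactate peak, against 33.2%, and 33.0% an H4K16la control peak, against 29.7%. Of such peaks in H4K8la control, 64.4% overlapped an H3K9la control peak, against 40.55% of its other peaks. An H4K8la lactate peak was overlapped by 49.9%, against 27.8%, and an H4K16la control peak by 43.8%, against 27.8%. The peaks with a high local background were also wider (median 617 against 492 bp in H3K9la control and 705 against 482 bp in H4K8la control), which by itself raises the chance of an overlap. The X chromosome held 1.54% of the peaks in H3K9la control and 1.84% with lactate, 2.28% and 2.92% for H4K8la, and 2.48% and 2.41% for H4K16la.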
